A study of Mus musculus with 47 samples.

How the data were processed

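Liver RNA of 47 C57B6/J mice was measured on 47 1-colour Agilent arrays, 1 array per mouse. Per the labels, the mice were 10 weeks old, ate chow and received pemafibrate, an agonist of the nuclear receptor PPARalpha, at 0.1 mg per kg per day or vehicle (0.5% carboxymethylcellulose) by gavage for 14 days. LKO mice lack PPARalpha in hepatocytes, and LWT mice are their controls with an intact receptor. Sex, genotype and treatment gave 8 groups of 6 mice, except that male LWT mice on pemafibrate were 5, without a replicate 2. The labels describe the samples as separate animals.

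The scanner values are spot intensity values on a linear scale from Agilent Feature Extraction 10.10.1.1, per the file headers, which also give mm9 probe positions. The intensity used here was the processed signal, already background-subtracted by that software per the file headers. A second table holds log2 values that the authors deposited without stating scale, centring or batch treatment. Its 37027 probes all matched array probes, 37 values were missing, and the column medians lay between 7.24 and 7.241. Across probes, its columns correlated at 0.9994 to 0.9999 with the log2 median signal of their own arrays, and 47 of 47 columns matched their own array best. The values thus ran as log2 quantile-normalized signal. Between the wash batches, the SD over probes of the mean difference was 0.00385 in that table and 0.126 in median signal normalized here. The smaller SD argues against deposited values that kept their wash batch difference. How the authors treated the batch is not given in the sources used here. The submitters' processing notes name limma without a version.

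The main values were log2 processed signal minus each array's 75th percentile over the probes. That percentile ran from 315 to 547 intensity units, with a median of 436. Between 60.6% and 68.9% of probes were well above background, the median background ran from 14 to 22, and no spot was saturated. Control spots were left out, and outlier spots, between 59 and 151 on an array, were set missing. For 55 probes a missing value was filled with the group mean. Of 56605 probes, 38744 were kept because they were well above background on at least a share of 0.5 of the arrays of 1 group or more. The number of arrays limits the precision: the median standard error of a log2 fold change between groups was 0.124 to 0.13, and 0.175 to 0.179 for differences of differences.

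Probe names came from the supplied mouse gene tables: 32994 probes by accession, 10224 by symbol, 520 by synonym and 9 by a symbol in other letter case, a step added after a first fit had been seen. The name in the scanner file was kept for 12858 probes, and 2064 names were replaced. Where a gene had more than 1 kept probe (8421 genes), the probe with the highest mean signal stood for it, giving 25474 genes. Near-identical genes, such as the Cyp4a, Sult2a and Acot families, may share probe signal, so their members are uncertain.

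Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, over all 8 groups in 1 model with wash batch as a covariate. The p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with 0.05 as the threshold. Every adjusted p for a gene is limma's, and every error beside a log2 fold change is its standard error (SE). Gene lists, 38 pathways and cell type marker sets, were tested with limma's camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Counts of list members past the threshold are given over all genes and adjusted over the list alone. A gene well above background on no array of a group has only a bound there: the bright group's mean against the mean of the lowest signal well above background on each array of the other, or the probe's own signal where higher. The comparisons were pemafibrate against vehicle in each sex and genotype, LKO against LWT vehicle mice in each sex, genotype by treatment in each sex, sex by treatment, sex by genotype, and females against males in LWT vehicle mice.

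The tests, the lists and the rule for naming genes were set before the data were examined. The rule took the 10 largest rises and falls per comparison among genes with official-looking symbols, the 4 list members with the largest changes past the threshold (or the member with the smallest p), a fixed roster of genes, and the 10 smallest p-values for the differences of differences and for pemafibrate in LKO mice. Genes named in 1 comparison may be given in another. Some genes that the rule takes are not reported here. Alternatives were quantile normalization, normexp background correction with offset 50, median signal, the authors' values, no filter or a stricter filter on dim probes, means of probes, no wash batch, slide as a fixed or random block, the replicate number as a block, only the groups compared, each wash batch alone and each mouse left out. Gene names without the letter-case step, the data without slide 1 and, for the gene lists, wash batch 2 alone were added after seeing the data; for gene lists wash batch 1 alone was set before. The tests were tested on simulated data with 200 changed genes among 25474. For pemafibrate in LWT males, 64.2% of 1.5-fold, 83.6% of 2-fold and 97% of 4-fold changes were recovered, with 4.1% of calls false. For sex by treatment the shares were 52.2%, 76.1% and 89.4%, with 5.8% of calls false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

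Array quality was checked before the comparisons. Pairs of mice of a group, 115 in number, correlated at 0.9868 to 0.9942 across genes, which are not independent replicates, and differed with an SD of 0.395 to 0.596, so no array was a copy of another. The first principal component held 31.7% of the variance and followed sex, which explained a share of 0.975 of it. The next held 15.8% and followed the groups (0.981). The third, with 4.3%, followed slide (0.702), and the arrays of slide 1 lay apart on a component. Wash batch 1 held 4 slides and batch 2 held 2, and each slide held about 1 array of each group.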

Results

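Gene expression was profiled in livers of 47 mice from a design that crossed sex, hepatocyte PPARalpha and pemafibrate. Each group held 6 mice, except male LWT mice on pemafibrate (n = 5). PPARalpha is a nuclear receptor that switches on genes of fatty acid oxidation, and pemafibrate is a selective agonist of it. The LKO mice lack the receptor in hepatocytes and the LWT mice retain it. Levels below are log2 signal relative to each array's 75th percentile, as mean ± SD over mice. Between 60.6% and 68.9% of probes on an array were well above background, and the number of arrays limits the precision.

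The genotype labels were first set against Ppara itself. In vehicle mice the Ppara probe read 5.44 ± 0.17 in LWT and 4.66 ± 0.46 in LKO males (n = 6 each), and 5.81 ± 0.17 in LWT and 4.95 ± 0.07 in LKO females (n = 6 each). The fall was −0.78 (SE 0.14, adjusted p = 0.00033) in males and −0.86 (SE 0.14, adjusted p = 3.82e-05) in females. Over the alternatives adjusted p ran from 1.92e-05 to 0.281 in males and from 5.62e-06 to 0.0995 in females. The call was lost in males with only the compared groups in the model (adjusted p = 0.0642) and within wash batch 2 alone in males (0.281) and females (0.0995). The probe lies at mm9 chromosome 15, positions 85632110 to 85632169, and a second Ppara probe at 85637193 to 85637252 read −0.93 in males and −0.91 in females. Whether either position lies in the deleted part is not given in the sources used here, so these probes may read transcript that remains. Sex labels were set against Xist, the RNA that silences an X chromosome, and Ddx3y, a Y-linked gene. Mean Xist levels ran from 3.96 to 4.13 in the 4 female groups and Xist was well above background in no male group, while Ddx3y ran from −0.92 to −0.74 in the male groups and was well above background in no female group.

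The first question was what pemafibrate did to liver gene expression where hepatocytes had the receptor. In LWT males genes that break down fatty acids in peroxisomes, mitochondria and microsomes rose with the drug. Ehhadh, a peroxisomal beta-oxidation enzyme, rose from 3.58 ± 0.18 (n = 6) to 7.79 ± 0.35 (n = 5), a log2 fold change of 4.19 (SE 0.20, adjusted p = 1.44e-19), and every treated mouse (7.47 or more) lay above every vehicle mouse (3.80 or less). Cyp4a10 and Cyp4a14, which omega-hydroxylate fatty acids, rose by 5.90 (SE 0.48, adjusted p = 3.21e-12) and 6.55 (SE 0.40, adjusted p = 9.22e-16). Where a group lies near background, the fold can depend on the background correction, and Cyp4a14 changed by 3.98 with normexp. Complement and coagulation genes moved the other way. The Ehhadh probe lies at mm9 chromosome 16, positions 21761914 to 21761973, and the Cyp4a14 probe at chromosome 4, 115168609 to 115168668.

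By list, all 25 measured genes of mitochondrial fatty acid oxidation rose in LWT males, also 25 when adjusted over the list alone, with a median log2 change of 0.70 (camera adjusted p = 1.37e-58). Uncoupling proteins Ucp2 (1.85) and Ucp3 (1.80) and the thioesterase Acot2 (4.35) were among its largest rises. Of 30 canonical PPARalpha targets, 25 rose and none fell (27 and 0 adjusted over the list alone), with a median of 1.26 and adjusted p = 5.56e-56. Among them the fatty acid translocase Cd36 rose by 3.02 (SE 0.21), the pantetheinase Vnn1 by 3.75 (SE 0.40), the lipid droplet coat Plin2 by 1.02 (SE 0.12) and the carnitine palmitoyltransferase Cpt1a by 0.38 (SE 0.12, adjusted p = 0.0234). Among the 5 targets that did not pass were Pdk4 (0.98, SE 0.38, adjusted p = 0.0937) and Fgf21 (1.34, SE 0.64, adjusted p = 0.194). Pdk4 passed with the replicate number as a block (1.09, adjusted p = 0.0371) and without vehicle replicate 2 (0.0228), and over all alternatives its adjusted p ran from 0.0228 to 0.448. Fgf21 passed with normexp background correction (adjusted p = 0.011), median signal (0.0215) and the authors' values (0.0193), and over all alternatives its adjusted p ran from 0.011 to 0.66. Peroxisomal genes rose in 26 of 36 (29 rose and 1 fell adjusted over the list alone; adjusted p = 6.62e-37), including the transferase Crat by 2.25 and the fatty acid transporter Abcd2 by 3.27 (1.47 with normexp). Ketogenesis genes rose in 4 of 7 (4 rose and 1 fell adjusted over the list alone; adjusted p = 2.37e-06), among them the thiolase Acat1 (0.74). Genes of fatty acid uptake and lipid droplets rose in 16 of 30 (17 adjusted over the list alone; adjusted p = 1.29e-13). Of the omega-hydroxylation list 6 of 15 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 3.05e-06).

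Sterol and fatty acid synthesis genes also rose in LWT males. Of 24 cholesterol synthesis genes 14 rose (21 adjusted over the list alone), with a median of 0.64 and adjusted p = 6.71e-13, though adjusted p = 0.0983 with an estimated correlation. Nsdhl rose by 1.18 (SE 0.20) and Pmvk by 0.98 (SE 0.21). Of 25 genes of fatty acid and triglyceride synthesis 9 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 1.57e-05, and adjusted p = 0.146 with an estimated correlation), with Elovl5, which elongates polyunsaturated fatty acids, up by 1.5 (SE 0.16). Retinoid genes rose in 6 of 13 and fell in 2, with the same counts adjusted over the list alone (adjusted p = 0.000816, and adjusted p = 0.0983 with an estimated correlation), and Retsat, a retinol saturase, rose by 2.29 (SE 0.17). Female-biased liver genes rose in 4 of 20 and fell in 1, the same adjusted over the list alone (adjusted p = 0.0455, and adjusted p = 0.419 with an estimated correlation). The call was also lost with normexp (0.0824), median signal (0.0521), the authors' values (0.0561), the stricter filter (0.052) and the replicate block (0.0562). It was lost too with only the groups compared (0.0881) and within wash batch 1 (0.0683) or 2 (0.112) alone. The female-biased list includes Acot3 and Abcd2, which are also in the peroxisomal list.

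Among genes that fell in LWT males, 19 of 36 complement and coagulation genes were lower and none higher (21 and 0 adjusted over the list alone), with a median of −0.24 (adjusted p = 3.16e-14). The terminal complement components C8b (−0.92, SE 0.17) and C9 (−0.91, SE 0.19) led. Interferon response genes fell in 11 of 16 (13 adjusted over the list alone; adjusted p = 9.06e-10, and adjusted p = 0.0983 with an estimated correlation), with Irf7, an interferon regulatory factor, at −0.77 (SE 0.15). Acute phase genes fell in 6 of 24 and rose in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.000982, and adjusted p = 0.419 with an estimated correlation), with Saa3 at −1.31 (SE 0.24). Markers of Kupffer cells, the liver's resident macrophages, fell beside these immune groups in 9 of 15 (12 adjusted over the list alone; median −0.46, adjusted p = 5e-07, and adjusted p = 0.146 with an estimated correlation), including Vsig4 (−0.56) and Cd5l (−0.58). T and NK cell markers fell in 1 of 10 (5 adjusted over the list alone; adjusted p = 0.00152, and adjusted p = 0.272 with an estimated correlation). Stellate cell markers fell in 3 of 14 (4 adjusted over the list alone; adjusted p = 0.00464, and adjusted p = 0.334 with an estimated correlation).

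Across all genes in LWT males, 1753 rose and 1247 fell, and 824 of these 3000 changed at least 1.5-fold. Large rises outside the lists included Mogat1, a monoacylglycerol acyltransferase (4.26, SE 0.19), Rad51b (5.95, SE 0.33, and 4.10 with normexp) and Krt23 (4.37, SE 0.37), and the drug-metabolizing Cyp2b10 rose by 2.66 (SE 0.47). Slc35f1 was not well above background in vehicle males and was at least 9.19-fold higher with the drug by the processed signal, against a log2 change of 1.02 with normexp background correction. The apolipoprotein Apoa4 fell by 2.23 (SE 0.27), and Wif1, an inhibitor of Wnt ligands, was at least 6.43-fold lower by the processed signal. The Wif1 call was lost in 1 of 27 alternatives, normexp background correction (−0.57, with adjusted p from 9.75e-07 to 0.0666 over the alternatives). The number past the threshold was 1454 within wash batch 1 alone and 496 within batch 2 alone, where the calls of C9, Saa3, Vsig4, Cd5l, Pmvk and Cyp2b10 were lost. The Cpt1a call was lost in 9 of 27 alternatives, with adjusted p from 0.0185 to 0.286.

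In LWT females the same question also gave higher fatty acid oxidation genes, together with changes of sex-biased liver genes. Ehhadh rose from 4.56 ± 0.40 to 8.02 ± 0.39 (n = 6 each), by 3.46 (SE 0.19, adjusted p = 9.19e-18). Cyp4a12a and Cyp4a12b, omega-hydroxylases normally prominent in male liver, rose by 7.35 (SE 0.32, adjusted p = 4.99e-21) and 7.0 (SE 0.29, adjusted p = 2.7e-21). Vehicle levels were low (−5.40 for Cyp4a12a), and over the alternatives the folds ran from 4.74 to 8.36 and from 4.79 to 7.97. Cyp4a10 rose by 2.82 (SE 0.46, adjusted p = 1.11e-05). Cyp4a14 was already high in vehicle females and read 1.27 ± 0.84 without and 1.61 ± 0.22 with the drug, a difference of 0.34 (SE 0.38, adjusted p = 0.624).

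All 25 mitochondrial oxidation genes again rose in LWT females, also 25 adjusted over the list alone (median 0.75, adjusted p = 1.54e-48), and 25 of 30 canonical targets rose with none lower, the same adjusted over the list alone (median 1.20, adjusted p = 9.91e-34). Peroxisomal genes rose in 28 of 36 (30 adjusted over the list alone; adjusted p = 7.02e-31), including Acaa1b by 1.86. Ketogenesis genes rose in 5 of 7, the same adjusted over the list alone (adjusted p = 2.72e-06), and uptake and droplet genes in 15 of 30 (16 adjusted over the list alone; adjusted p = 6.13e-13). In that last group lipoprotein lipase, Lpl, rose by 3.14 (SE 0.24), Cd36 by 2.95 (SE 0.20) and the fatty acid transporter Slc27a1 by 2.15 (SE 0.14). Another Lpl probe did not follow, at −0.03, while 5 of its 6 probes read 2.79 to 3.14. Cpt1a rose by 0.33 (adjusted p = 0.0268), and Pdk4 (0.65, adjusted p = 0.239) and Fgf21 (0.51, adjusted p = 0.645) did not pass. Of the omega-hydroxylation list 6 of 15 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.00399, and adjusted p = 0.0838 with an estimated correlation).

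Female-biased liver genes fell in LWT females: 10 of 20 were lower and 1 higher, the same adjusted over the list alone, with a median of −0.50 (adjusted p = 6.81e-05, and adjusted p = 0.0879 with an estimated correlation). The cytochrome Cyp3a44 fell by 4.43 (SE 0.38), and A1bg (−2.02, SE 0.37) fell too. Male-biased Hsd3b5 (−3.39, SE 0.56) and Slco1a1 (−1.77, SE 0.31) also fell. Of 10 genes of growth hormone and STAT5 signalling 3 fell (4 adjusted over the list alone; adjusted p = 0.0135, and adjusted p = 0.0879 with an estimated correlation), among them the receptor Ghr at −0.49 (SE 0.08). Retinoid genes rose in 5 of 13 and fell in 1, the same adjusted over the list alone; their median was −0.01, their mean 0.29 and the test gave a rise (adjusted p = 0.00405, and adjusted p = 0.16 with an estimated correlation).

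Complement and coagulation genes fell in 23 of 36 in LWT females (30 adjusted over the list alone; median −0.33, adjusted p = 3.5e-19), with C9 at −1.5 (SE 0.18), F11 at −0.94 (SE 0.13) and C8b at −0.94 (SE 0.17). Interferon genes fell in 8 of 16 (11 adjusted over the list alone; adjusted p = 9.38e-05, and adjusted p = 0.3 with an estimated correlation), and acute phase genes in 8 of 24 with 2 higher, the same adjusted over the list alone (adjusted p = 0.0057, and adjusted p = 0.498 with an estimated correlation). Beside them Kupffer cell markers fell in 7 of 15 and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00176, and adjusted p = 0.398 with an estimated correlation). T and NK cell markers fell in 6 of 10 (9 adjusted over the list alone; adjusted p = 0.000384, and adjusted p = 0.177 with an estimated correlation). Sinusoidal endothelial markers fell in 5 of 10 (6 adjusted over the list alone; adjusted p = 0.00405, and adjusted p = 0.177 with an estimated correlation), and stellate cell markers in 4 of 14, the same adjusted over the list alone (adjusted p = 0.0151, and adjusted p = 0.398 with an estimated correlation).

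In total 2689 genes rose and 2264 fell in LWT females, and 1359 of these 4953 changed at least 1.5-fold. Mogat1 rose by 5.49 (SE 0.18), the cytokine antagonist Il1rn by 2.55 (SE 0.31, and 1.65 with normexp), and the protease Ctse was at least 26.8-fold higher by the processed signal (log2 change 1.70 with normexp). Apoa4 (−3.05, SE 0.26), the phosphatidate phosphatase Lpin1 (−1.99, SE 0.39), pyruvate kinase Pklr (−1.83, SE 0.24) and Apoc3 (−0.35, SE 0.08, and −0.69 as the mean of its probes) fell. Each wash batch alone gave fewer, 2452 in batch 1 and 1079 in batch 2, and in batch 2 the calls of Cyp4a10, A1bg, Lpin1 and Apoc3 were lost. The Cpt1a call was lost in 5 of 28 alternatives, with adjusted p from 0.0162 to 0.319.

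**Figure D1:**
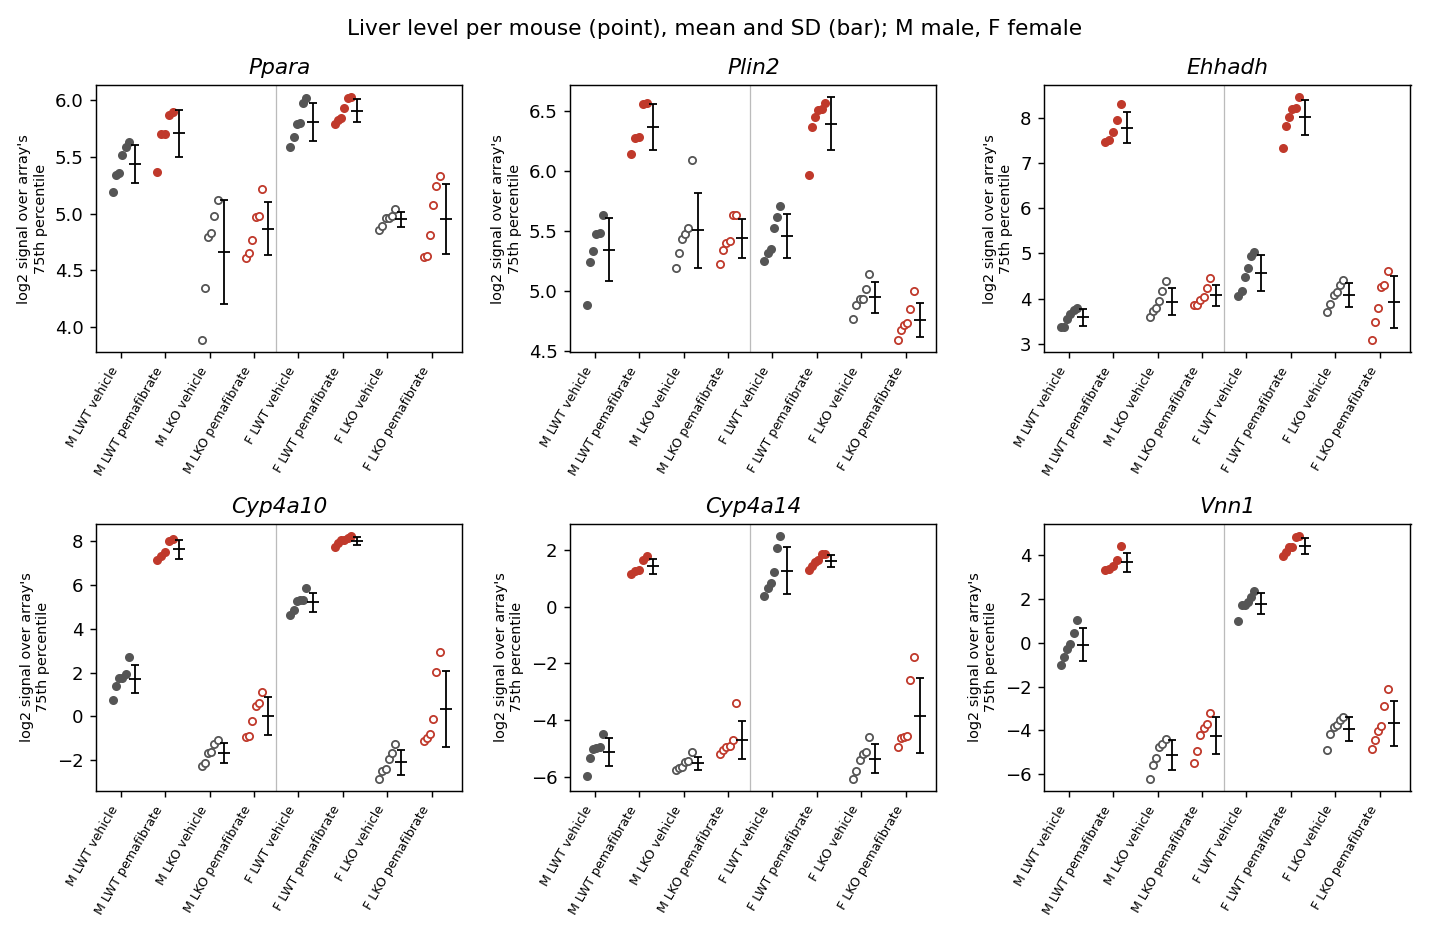
Log2 signal of Ppara, Plin2, Ehhadh, Cyp4a10, Cyp4a14 and Vnn1 relative to each array's 75th percentile, for each mouse (points) with group mean and SD (bars), over the 8 groups. Ehhadh rose with pemafibrate from 3.58 to 7.79 in LWT males and from 4.56 to 8.02 in LWT females, and read 4.08 without and 3.92 with it in LKO females.

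A second question was whether pemafibrate acted without hepatocyte PPARalpha. In LKO males no gene passed (0 genes with limma, 1077 at an unadjusted p under 0.05), and Cyp4a10 read −1.67 ± 0.46 without and 0.02 ± 0.85 with the drug (n = 6 each), a difference of 1.69 (SE 0.46, adjusted p = 0.989). The smallest p-values belonged to Klhl28 (−0.22, SE 0.05) and Zbtb6 (−0.26, SE 0.06), both with adjusted p = 0.567. Cyp4a14 read 0.83 higher (SE 0.38) and Vnn1 0.88 higher (SE 0.38), each with adjusted p = 0.989. Of 38 lists 2 passed, and none did with an estimated correlation. The 25 cell cycle genes shifted down with a median of −0.24 and 0 members past the threshold, also 0 adjusted over the list alone (adjusted p = 1.87e-08, and adjusted p = 0.967 with an estimated correlation). Immediate early genes had a median of −0.40 with 0 of 13 past the threshold, also 0 adjusted over the list alone (adjusted p = 0.0112, and adjusted p = 0.967 with an estimated correlation). The same LKO vehicle males enter LKO against LWT below, where both lists shifted up, so the opposite shifts are not separate findings.

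In LKO females 6 genes rose and 4 fell. Cyp4a10 rose from −2.11 ± 0.58 to 0.33 ± 1.74 (n = 6 each), by 2.44 (SE 0.46, adjusted p = 0.0177), and Cyp4a31 by 2.24 (SE 0.43, adjusted p = 0.0177), each lost in 9 of 28 alternatives, while Ehhadh (−0.16, SE 0.19, adjusted p = 0.855) and Vnn1 (0.26, SE 0.38, adjusted p = 0.894) did not pass. Dnaic1, a ciliary dynein chain, rose by 0.95 (SE 0.15, adjusted p = 0.00227, lost in 2 of 28), Mxd1 by 0.58 (lost in 4 of 28) and Omd by 1.20 (lost in 13 of 28). G6pdx, the first enzyme of the pentose phosphate pathway, fell by 0.78 (SE 0.14, adjusted p = 0.0125, lost in 7 of 28) and the class I antigen gene H2-Q5 fell by 0.47 (lost in 16 of 28), and Gm28548 was at least 4.06-fold lower by the processed signal (lost in 7 of 28, with −0.44 with normexp). Of 38 lists 12 passed, and omega-hydroxylation was the 1 that did with an estimated correlation. Omega-hydroxylation genes rose in 2 of 15 (4 adjusted over the list alone; adjusted p = 4.79e-05, and adjusted p = 0.0336 with an estimated correlation). Genes of fatty acid and triglyceride synthesis had a median of −0.36 with 0 of 25 past the threshold, and 10 fell when adjusted over the list alone (adjusted p = 1.2e-10, and adjusted p = 0.0628 with an estimated correlation). Kupffer cell markers shifted down beside them, with 0 of 15 past the threshold, also 0 adjusted over the list alone (median −0.23, adjusted p = 2.59e-06, and adjusted p = 0.395 with an estimated correlation). They shifted up for LKO against LWT in females, which shares these LKO vehicle mice. Markers of hepatocytes (median 0.09, adjusted p = 0.00184) and of blood (median 0.42, adjusted p = 0.000163) shifted up, with 0 of 10 and 0 of 7 past the threshold (2 and 1 adjusted over the list alone), each with adjusted p = 0.395 with an estimated correlation. The hepatocyte call was also lost with median signal (adjusted p = 0.052) and the authors' values (0.0768). With only these 2 groups in the model none of the 10 genes passed (Cyp4a10 adjusted p = 0.606, Dnaic1 0.404) and 1 other gene did, and within wash batch 2 no gene passed. The number ran from 3 without vehicle replicate 1 to 30 without pemafibrate replicate 5, and Cyp4a10 no longer passed without pemafibrate replicate 3 (adjusted p = 0.115) or 4 (0.0815) or without vehicle replicate 1 (0.0688), 4 (0.0591) or 6 (0.0788).

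Tested directly, the response differed between genotypes for 925 genes in males, 289 with a higher and 636 with a lower change in LKO, and for 3009 in females (1208 and 1801). The rise of Ehhadh was smaller in LKO in males (difference −4.05, SE 0.27, adjusted p = 5.13e-14) and in females (−3.62, SE 0.26, adjusted p = 4.83e-13). Mogat1 differed by −4.17 in males and −5.40 in females, Acot2 by −4.08 and −3.58, the mitochondrial isomerase Eci1 by −1.26 and −1.32, and Cyp4a14 in males by −5.72 (SE 0.56, and −3.76 with normexp). Canonical targets responded less in LKO for 21 of 30 in males (24 adjusted over the list alone; adjusted p = 2.05e-58) and 22 of 30 in females (22, with 1 the other way, adjusted over the list alone; adjusted p = 1.07e-25). Mitochondrial oxidation genes did so in 23 and 24 of 25 (24 in each sex adjusted over the list alone; adjusted p = 5.99e-62 and 1.49e-40), and peroxisomal genes in 21 and 26 of 36 (25 and 29 adjusted over the list alone; adjusted p = 5.18e-41 and 6.42e-31).

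The falls of complement and coagulation genes were also smaller in LKO, in 8 of 36 genes in males (16 adjusted over the list alone; adjusted p = 8.68e-13) and 22 of 36 in females (26 adjusted over the list alone; adjusted p = 6.12e-19), with C9 in females differing by 1.89 (SE 0.25). Beside them Kupffer cell markers differed upward in males, in 1 of 15 (1 adjusted over the list alone; median 0.43, adjusted p = 4.73e-05, and adjusted p = 0.267 with an estimated correlation). T and NK cell markers did in females, in 1 of 10 (2 adjusted over the list alone; median 0.49, adjusted p = 0.0208, and adjusted p = 0.419 with an estimated correlation). Apoa4 differed by 1.91 (SE 0.38) in males and 2.86 (SE 0.37) in females. In females the female-biased Cyp3a44 (3.56, SE 0.54) differed, with 7 of 20 genes of its list higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.367 with an estimated correlation). Within wash batch 1 alone 377 genes passed in males and 1502 in females, and within batch 2 alone 40 and 301, where the calls of Cyp4a14 and Apoa4 in males and C9 in females were lost.

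**Figure D2:**
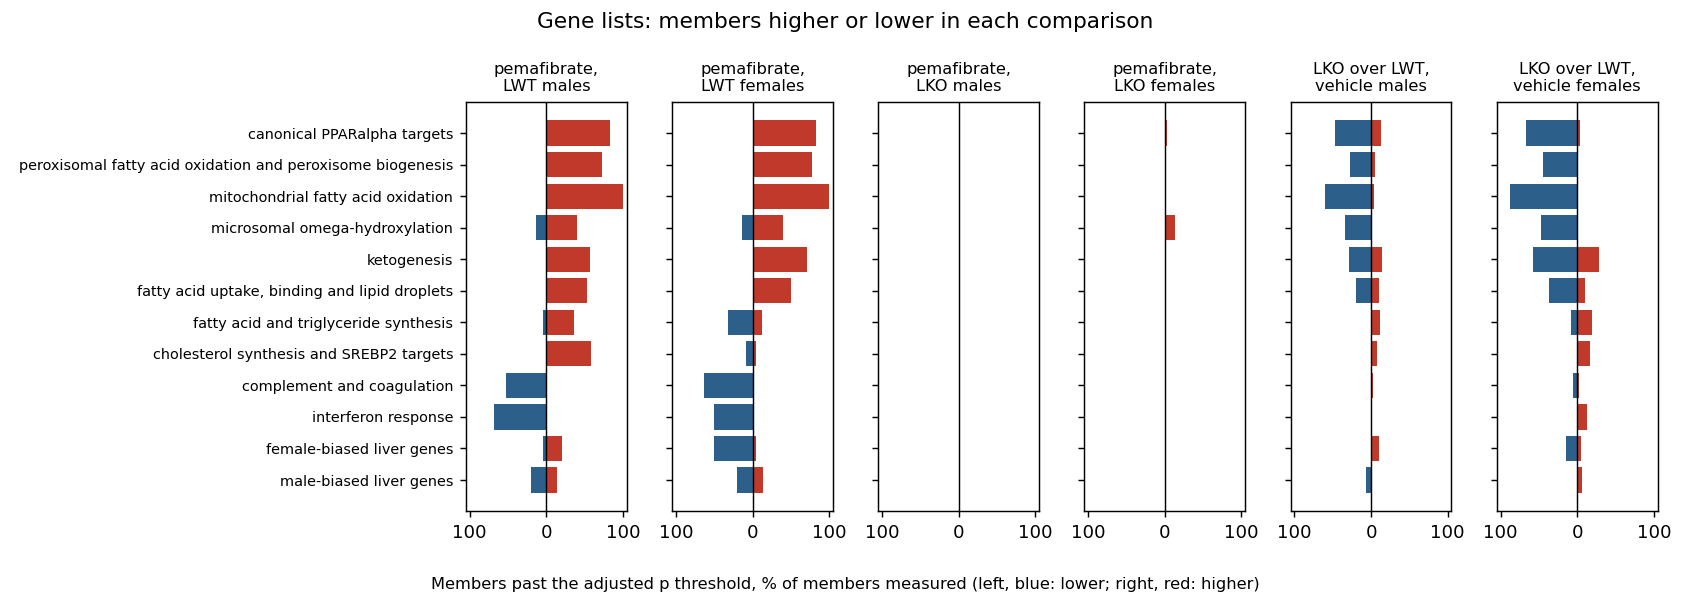
Bars give, for 12 gene lists in 6 comparisons, the percent of measured members past the adjusted p threshold, lower to the left in blue and higher to the right in red. All 25 mitochondrial fatty acid oxidation genes were higher with pemafibrate in LWT males and in LWT females, and the LKO male panel is empty, since 0 genes passed there.

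The third question was what loss of hepatocyte PPARalpha did without the drug. In vehicle males, mitochondrial oxidation genes were lower: 15 of 25 fell and 1 rose (17 and 1 adjusted over the list alone; median −0.33, adjusted p = 1.7e-27). Vnn1 fell from −0.08 ± 0.74 to −5.12 ± 0.69 (n = 6 each), a change of −5.04 (SE 0.38, adjusted p = 7.4e-13), which ran from −5.29 to −2.69 over the alternatives, and LKO males were well above background on 5 of 6 arrays. The carnitine carrier Slc25a20 (−1.54, SE 0.12) and the acyl-CoA dehydrogenase Acadvl (−1.06, SE 0.05) fell as well. Fgf21, a fasting hormone of the liver, was also lower, but it was well above background on 1 of 6 LKO male arrays, so its fold is uncertain and ran from −4.78 to −1.06 over alternatives. Pdk4, which restrains glucose oxidation, rose by 2.52 (SE 0.37), and so did the thioesterases Acot1 (2.21, SE 0.24), Acot2 (1.60, SE 0.22) and Acot3 (2.56, SE 0.35). These 4 were the canonical targets that rose, against 14 that fell (4 and 15 adjusted over the list alone; adjusted p = 7.08e-07, and adjusted p = 0.138 with an estimated correlation).

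In vehicle LKO males 10 of 36 peroxisomal genes fell and 2 rose (14 and 3 adjusted over the list alone; adjusted p = 9.13e-06, and adjusted p = 0.386 with an estimated correlation). Omega-hydroxylation genes fell in 5 of 15 (6, with 1 higher, adjusted over the list alone; adjusted p = 0.00172, and adjusted p = 0.138 with an estimated correlation), with Cyp4a10 at −3.39 (SE 0.46). Ketogenesis genes fell in 2 of 7 and rose in 1 (4 and 2 adjusted over the list alone; adjusted p = 0.0219, and adjusted p = 0.477 with an estimated correlation). Cholesterol synthesis genes rose in 2 of 24 (9 adjusted over the list alone; adjusted p = 7.08e-07, and adjusted p = 0.505 with an estimated correlation). Kupffer cell markers shifted up, with 1 of 15 past the threshold (2 adjusted over the list alone; median 0.19, adjusted p = 0.00428, and adjusted p = 0.532 with an estimated correlation), and within wash batch 2 alone they pointed down (adjusted p = 0.821). Immediate early genes, which respond to handling and stress, had a median of 0.90 with 1 of 13 higher, and also 1 adjusted over the list alone (adjusted p = 0.00135, and adjusted p = 0.505 with an estimated correlation). Cpt1a (−0.39, adjusted p = 0.0392) fell, a call lost in 13 of 28 alternatives, and Ehhadh read 0.35 (adjusted p = 0.353). In all 374 genes rose and 466 fell. With normexp background correction 2886 genes passed, 669 higher and 2217 lower, a share of 23.2% higher against 44.5% here, and the peroxisomal (adjusted p = 0.19), omega-hydroxylation (0.102) and ketogenesis (0.496) lists no longer passed. With only these groups in the model 448 genes passed, within wash batch 1 alone 396 and within batch 2 alone 142, where the Cyp4a10 call was lost.

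In vehicle females the same gene groups were lower in LKO. Cyp4a10 fell from 5.21 ± 0.43 to −2.11 ± 0.58, a change of −7.32 (SE 0.46, adjusted p = 6.26e-16), and Cyp4a14 from 1.27 ± 0.84 to −5.37 ± 0.52, a change of −6.64 (SE 0.38, adjusted p = 5.11e-17) that ran from −6.85 to −4.06 over the alternatives. Of 30 canonical targets 20 fell and 1 rose (25 and 1 adjusted over the list alone; median −0.66, adjusted p = 8.45e-46), the riser being Pdk4 (1.18, SE 0.37, adjusted p = 0.0414). Mitochondrial oxidation genes fell in 22 of 25 (24 adjusted over the list alone; median −0.63, adjusted p = 6.53e-62), with Slc25a20 at −2.35 (SE 0.12) and Acadvl at −1.33 (SE 0.05). Peroxisomal genes fell in 16 of 36 (21, with 1 higher, adjusted over the list alone; adjusted p = 4.29e-24), with Ech1 at −1.92 and Eci2 at −1.75. Omega-hydroxylation genes fell in 7 of 15 (8 adjusted over the list alone; adjusted p = 7.69e-10).

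Genes of uptake and droplets fell in 11 of 30 in vehicle LKO females and rose in 3 (13 and 6 adjusted over the list alone; adjusted p = 6.94e-06), with the droplet coat Plin5 at −2.46 (SE 0.18), the lipase inhibitor Angptl4 at −2.54 (SE 0.33) and Fitm1, which promotes droplet formation, at least 26.3-fold lower by the processed signal (log2 change −1.91 with normexp). Ketogenesis genes fell in 4 of 7 and rose in 2 (5 and 2 adjusted over the list alone; adjusted p = 0.000298), with Fgf21 lower by an uncertain fold (−4.54 to −1.66 over alternatives), since it was well above background on 4 of 6 LKO female arrays. Cholesterol synthesis genes rose in 4 of 24 (9 adjusted over the list alone; adjusted p = 3.18e-06, and adjusted p = 0.518 with an estimated correlation). Interferon genes rose in 2 of 16 (4 adjusted over the list alone; adjusted p = 4.43e-05, and adjusted p = 0.518 with an estimated correlation), with Oasl1 at 1.42 (SE 0.28). Kupffer cell markers shifted up beside them with 0 of 15 past the threshold, also 0 adjusted over the list alone (median 0.26, adjusted p = 0.000438, and adjusted p = 0.521 with an estimated correlation). Pck1, the gluconeogenic carboxykinase (−1.18, SE 0.27), Nr1d1, a repressor of the circadian clock (−1.40, SE 0.35), and the orphan receptor Esrrg (−5.27, SE 0.41, from −5.58 to −2.06 over the alternatives) fell. The Nr1d1 call was lost without slide 1 (−1.01) and within wash batch 1 alone, with adjusted p from 0.00285 to 0.224 over the alternatives, that of Oasl1 within batch 1 alone and that of Pck1 within batch 2 alone. In all 748 genes rose and 943 fell, against 569 past the threshold within wash batch 1 alone and 202 within batch 2 alone. The balance of rises and falls depended on the scaling. Here 44.2% of calls were higher, against 51.9% with quantile normalization, 52.2% with median signal and 52.9% with the authors' values. The Pdk4 call was lost in 14 of 28 alternatives, with adjusted p from 0.00546 to 0.78.

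Whether the drug response differed between the sexes was tested as a difference of differences in LWT mice, and 75 genes passed, 34 with a higher and 41 with a lower change in females. Cyp4a12a (6.33, SE 0.46, adjusted p = 7.4e-13) and Cyp4a12b (6.00, SE 0.42, adjusted p = 4.18e-13) had a larger log2 change in females, as did Lpl (2.10, SE 0.34, adjusted p = 0.000489). Cyp4a12a started from −5.4 in vehicle females and reached 1.95 with the drug, still below the 5.46 of vehicle males. With normexp the Cyp4a12a and Cyp4a12b differences were 3.73 and 3.80. Cyp4a14 (−6.21, SE 0.56, and −3.66 with normexp), Cyp4a10 (−3.08, SE 0.66) and Acot3 (−3.21, SE 0.50) had a smaller change in females, where their vehicle levels were higher. The Cyp4a10 difference gave adjusted p = 0.0508 without male pemafibrate replicate 3. Female-biased genes had a lower change in females in 6 of 20 (12 adjusted over the list alone; median −1.19, adjusted p = 5.28e-19), among them Cyp3a44 (−4.25, SE 0.55). Cholesterol synthesis genes had a lower change in 3 of 24 (8 adjusted over the list alone; median −0.55, adjusted p = 3.73e-15, and adjusted p = 0.136 with an estimated correlation), and genes of fatty acid and triglyceride synthesis in 1 of 25 (12 adjusted over the list alone; adjusted p = 2.38e-10, and adjusted p = 0.0854 with an estimated correlation). Canonical targets had a lower change in 3 of 30 (6, with 1 higher, adjusted over the list alone; adjusted p = 6.44e-05, and adjusted p = 0.248 with an estimated correlation), and Ehhadh read −0.73 (SE 0.27, adjusted p = 0.338). Within wash batch 1 alone 21 genes passed and within batch 2 alone 10, and 47 passed without slide 1. The calls of Cyp4a10 and Lpl were lost in each batch alone, and those of Cyp4a14, Acot3 and Cyp3a44 in batch 2 alone.

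Across genes, which are not independent replicates, the log2 changes with pemafibrate in LWT males and females correlated at r = 0.572 (Spearman's rho 0.50). Of genes past the threshold, 1259 rose in both sexes where independent lists would share 185.0, 712 fell in both against 110.8, and 1 moved in opposite directions.

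**Figure D3:**
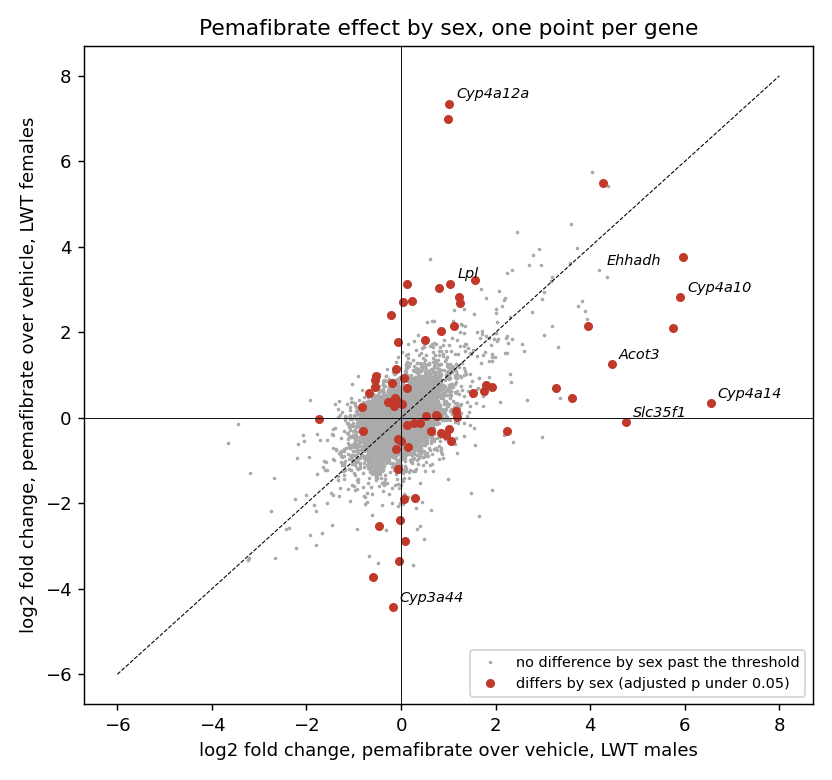
Log2 fold change with pemafibrate over vehicle in LWT males (horizontal) and LWT females (vertical), each point a gene, with the dashed line marking equal change and the 75 genes whose response differed by sex in red. Cyp4a12a lies far above the line, at 7.35 in females, and Cyp4a14 far below it, at 6.55 in males and 0.34 in females.

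The effect of receptor loss also differed by sex, for 53 genes, 44 of them lower in females. Lower here means a more negative log2 change, not a weaker one: in LKO, Cyp4a10 changed by −7.32 in females and −3.39 in males, and Cyp4a14 by −6.64 and −0.4. The test of sex by treatment above uses the same LWT vehicle mice, so genes that pass in both are not separate findings. The LKO effect on canonical targets was lower in females than in males for 10 of 30 (18 adjusted over the list alone; median −0.68, adjusted p = 9.84e-41), among them Cyp4a14 (−6.24, SE 0.54, adjusted p = 3.82e-10, and −3.78 with normexp), Cyp4a10 (−3.93, SE 0.65, adjusted p = 0.000585) and Retsat (−1.81, SE 0.23, adjusted p = 3.78e-06). The 10 include Acot1 (−2.86, SE 0.34), Acot2 and Acot3 (−3.00, SE 0.49), which LKO raised in males. The effect was also lower in females for mitochondrial oxidation genes in 4 of 25 (17 adjusted over the list alone; adjusted p = 5.6e-29), peroxisomal genes in 6 of 36 (15 adjusted over the list alone; adjusted p = 1.2e-17), omega-hydroxylation genes in 3 of 15 (5 adjusted over the list alone; adjusted p = 3.07e-07), and uptake and droplet genes in 1 of 30 (6, with 1 the other way, adjusted over the list alone; adjusted p = 4.96e-05). Fitm1 gave −3.36 (SE 0.44), where LKO females were not well above background, and 0.10 (adjusted p = 0.945) with normexp background correction, and its call was also lost with median signal (−0.60) and the authors' values (−0.59). Across genes the LKO effects of the sexes correlated at 0.523, with 167 genes higher in both (11 by independent lists), 282 lower in both (17.3) and 3 opposite. Within wash batch 1 alone 14 genes passed and within batch 2 alone 6. The Acot3 call was lost in each batch alone, and those of Cyp4a14, Cyp4a10, Retsat and Fitm1 in batch 2 alone.

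Set against each other, the pemafibrate effect in LWT mice and the LKO effect shared their vehicle mice. Across genes they correlated at −0.055 in males and −0.057 in females, where unchanged groups against the same vehicle mice gave a simulated 0.473 and 0.498. The covariances were −0.0056 and −0.0073 against simulated values of 0.0145 and 0.0147, a difference of −0.0201 and −0.0220. With the vehicle mice split into separate sets, the correlations were −0.196 and −0.160. Across sexes, which share no mice, pemafibrate in males against LKO in females gave −0.340 and the other pairing −0.134. Genes that rose with pemafibrate and were lower in LKO numbered 177 in males, where independent lists would share 32.1, and 342 in females (99.5). Shared vehicle mice by themselves favour genes that rise with both, so these were counted across sexes. Pemafibrate in males against LKO in females gave 43 that rose with both (51.5 by independent lists) and 361 that rose and were lower in LKO (64.9), and the other pairing gave 69 (39.5) and 196 (49.2). Within males Vnn1 read 3.75 with pemafibrate and −5.04 in LKO, and Acot2 4.35 and 1.60. The correlations in males and in females turned positive, to 0.044 and 0.06, with no filter on dim probes.

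Females against males gave the most genes past the threshold of the comparisons: 3170 were higher and 3979 lower in LWT vehicle females. Female-biased liver genes were higher in 19 of 20, also 19 adjusted over the list alone (median 6.08, adjusted p = 1.1e-48), with Cyp2b13 at least 2790-fold and Sult3a1 at least 2360-fold higher by the processed signal (log2 changes 8.07 and 7.87 with normexp). Male-biased genes were lower in 12 of 15 (13 adjusted over the list alone; median −3.40, adjusted p = 9.44e-22), with Cyp4a12a at −10.86 (SE 0.32, and −8.20 with normexp), Cyp4a12b at −10.41 (SE 0.29, and −8.14 with normexp) and Moxd1 at least 267-fold lower by the processed signal (log2 change −4.60 with normexp). Canonical PPARalpha targets were higher in females in 14 of 30 and lower in 1, the same adjusted over the list alone (median 0.34, adjusted p = 1.51e-08), with Cyp4a14 at 6.4 (SE 0.38, and 3.86 with normexp), Cyp4a10 at 3.5 (SE 0.46) and Acot3 at 6.31 (SE 0.35). Sinusoidal endothelial markers were higher in 9 of 10, also 9 adjusted over the list alone (median 0.44, adjusted p = 1.75e-09). Alone, wash batch 1 gave 4617 genes and batch 2 gave 2027.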

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

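The tests of male RNA, of a floor for Abcd2, of an action outside hepatocyte PPARalpha, of an LWT animal among LKO females, of time of day or feeding, and of a sex difference that needs hepatocyte PPARalpha were chosen after the result was seen. The others were set before.

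Some results differed between groups by a test of the difference itself. Genotype changed the response to pemafibrate for 925 genes in males and 3009 in females. For differences of differences, the residuals of a model without that difference were exchanged at random among the mice compared. Of 100 counts, the observed one included, only that 1 was as large in each sex. The highest of the others were 4 and 411, which argues against chance. Sex changed the response for 75 genes in LWT mice and the LKO effect for 53 genes. Again 1 of 100 such counts was as large, the observed one, with 9 and 0 as the highest of the others. Between the sexes Cyp4a10 (−3.08), Cyp4a14 (−6.21) and Lpl (2.10) differed in their response to pemafibrate, and Cyp4a10 (−3.93) and Cyp4a14 (−6.24) in the LKO effect. Both tests use the same LWT vehicle mice, so genes that pass in both are not separate findings. Among those vehicle mice Cyp4a14 read −5.13 in males and 1.27 in females. It read 1.43 and 1.61 in LWT mice on pemafibrate, and −5.53 and −5.37 in LKO vehicle mice. With an estimated correlation, the list of female-biased genes differed between the sexes in the response (adjusted p = 0.000327). In the LKO effect, canonical targets (2.18e-06), peroxisomal genes (0.00403), mitochondrial oxidation genes (0.00133), omega-hydroxylation genes (0.00139) and uptake and droplet genes (0.0144) did.

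For the other comparisons the mice themselves were split at random into groups of the same sizes, 100 splits with the real one included. Only the real split, 1 of 100, gave as many genes for pemafibrate in LWT males (3000, the highest other 1856) and females (4953, the highest other 1599). The same held for LKO against LWT in vehicle males (840, the highest other 236) and females (1691, the highest other 602), and for females against males (7149, the highest other 4035). This argues against chance for these, though 100 splits cannot show a share below 1 of 100. In each of these the highest other split differed from the real one by 1 mouse on a side. For pemafibrate in LKO females 2 of 100 splits gave at least 10 genes, the real one and another with 40. That share is small, but a wrong grouping called more genes than treatment did and none of the 10 genes passed with only these groups in the model, so chance is not taken as excluded there. For LKO males the real split gave 0 genes, which all 100 splits reach by construction, so this count decides nothing there; the highest other gave 38. The splits with 40 and 38 genes were the highest of their sets, where the median split gave 0 genes. Both held wash batch 1 equally, with 4 of its arrays on each side, and their cause was not tested.

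In pemafibrate-treated LWT females 10 of 20 female-biased genes fell (the list with adjusted p = 0.0879 with an estimated correlation) and Cyp4a12a rose, a shift that RNA of male livers would also bring. The Cyp4a12a level of 1.95 would need a male share of 8.7%, which would put Ddx3y at −4.29, and the measured level lay −3.84 from that, at −8.13 ± 0.21 with 0 of 6 arrays above background, which argues against such a mixture. In LKO females the 10 genes that fell had a median ratio of 0.15 to their change in LWT females, with an upper quartile of 0.35. This argues against an action of pemafibrate outside hepatocyte PPARalpha as the source of most of their fall. The 10 genes were picked by their fall in LWT females, which by itself lowers the ratio. Cyp4a12a was not part of this test, and in LKO females it read 1.2 higher with the drug (SE 0.32), against 7.35 in LWT females. Of the 6 genes with a lower change in females than in males, 3 were well above background on every LWT vehicle male array, and Abcd2 rose in LWT males (3.27, SE 0.34), which a floor could not bring, so for Cyp3a44 and Sult3a1 alone the sex difference and a floor in males cannot be told apart. Tested as genotype by treatment in females, 7 of the 10 genes that fell passed. The list did not with an estimated correlation (adjusted p = 0.367) or within wash batch 1 alone (0.203). An effect through hepatocyte PPARalpha on sex-biased genes may thus explain the fall of these 10 genes within females, as a hypothesis from these same data.

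Cyp4a10 and Cyp4a31 rose in pemafibrate-treated LKO females, and the rise lay mostly in replicates 3 and 4, with Cyp4a10 at 2.05 and 2.96 against −1.12 to −0.12 in the others. These 2 mice also stood apart on the first principal component (47.5 and 48.36 against 27.94 to 32.84). Still, every treated LKO female lay above every vehicle LKO female (−1.29 or less). In LKO males Cyp4a10 separated too (treated −0.96 or more, vehicle −1.1 or less), a difference of 1.69 (SE 0.46) that did not pass. An LWT animal among the treated LKO females is argued against by Ehhadh, which peaked at 4.61 in these 6 mice while treated LWT females lay at 7.35 or more. Receptor left in a small share of hepatocytes could bring the rise with 0.389% of the LWT response. It predicts rises of 4 other genes, and the median ratio of observed to predicted change was 0.58 with an error of 0.40 and a range from 0.01 to 1.39, so it cannot be told apart from a response without the receptor. An action of the drug outside hepatocytes was not tested.

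The LKO effect on canonical PPARalpha targets was lower (a more negative log2 change) in females than in males, for 10 of 30, of which Acot1, Acot2 and Acot3 had risen in LKO males. For the 25 of 30 members that were well above background on every vehicle array, a floor in males is argued against. As a list they kept camera p = 8.91e-08 with an estimated correlation. The members left out of this test were Cyp4a14, Fgf21, Vnn1, Aqp3 and Fitm1. Cyp4a14 read −5.13 ± 0.50 in LWT vehicle males, well above background on 5 of 6 arrays, so a floor in males stays open for it. A sex difference that needs hepatocyte PPARalpha cannot be told apart from others: among the 7 of these 10 targets that differed between the sexes in LWT mice, 2 (Acot3 and Fitm1) differed the same way in LKO mice, Acot1 differed the opposite way and 4 (Cyp4a10, Cyp4a14, Acot2 and Acadm) did not pass there, which does not show equal levels. The other 3 targets (Acaa1b, Retsat and Slc25a20) passed between the sexes in LKO mice alone. Time of day or feeding state of the vehicle groups stays open: the clock (adjusted p = 0.683) and glucose metabolism lists (0.211) missed the threshold, which does not show equal states.

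In 102 groups of a gene's levels tested for a mouse far from the others, 3 had one, and chance flags about 1 in 20 groups. Cyp4a14 in male LKO mice on pemafibrate read −3.41 in replicate 1 against −5.20 to −4.69 in the others, a gap of 0.718 of the range. Cpt1a in female LKO mice on pemafibrate read 5.61 in replicate 2 against 4.77 to 4.94, a gap of 0.8 of the range. Plin2 in female LWT mice on pemafibrate read 5.97 in replicate 1 against 6.37 to 6.57, a gap of 0.672 of the range.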

How the results depend on the processing

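The data without slide 1, gene names without the letter-case step and lists within wash batch 2 were alternatives chosen after seeing the data; the rest were set before. Of values of named genes under alternatives other than leaving out a mouse, 3131 kept direction and side of the threshold, 142 lost their call, 4 gained one and 3 reversed. For leaving out a mouse the numbers were 2818, 80, 2 and 1. Of list values 1221 kept their call, 83 lost it, most with an estimated correlation or in a wash batch alone, and 1 reversed. Signal near background limits dim genes. For pemafibrate in LWT females, 71 of 4953 genes past the threshold were well above background on no array of 1 group alone. Another 3 were so on no array of either group.

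Within wash batch 1 alone the genes past the threshold were 1454 (pemafibrate in LWT males), 2452 (LWT females), 396 (LKO against LWT males), 569 (females), 377 (genotype by treatment, males), 1502 (females), 21 (sex by treatment), 14 (sex by genotype) and 4617 (females against males). Within batch 2 alone they were 496, 1079, 142, 202, 40, 301, 10, 6 and 2027 in that order, and 0 for pemafibrate in LKO females. These hold fewer mice. Kupffer cell markers of LKO males pointed down within batch 2 (adjusted p = 0.821). With only the compared groups, 1 gene passed for pemafibrate in LKO females, none of the 10, and 448 for LKO males against LWT. Without slide 1, 1 gene passed in LKO males, 1 in LKO females and 47 for sex by treatment. Normexp gave 2886 genes for LKO against LWT males, 792 of them shared with the 840, and for pemafibrate in LKO females 75% of 8 calls were higher against 60% of 10. The cause was not tested.

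Fitm1 reversed for sex by genotype with normexp (0.098), Vnn1 for pemafibrate in LKO females within batch 1 (−0.06) and without female LKO pemafibrate replicate 4 (−0.068); leaving out single mice gave −0.068 to 0.484, and Ehhadh there within batch 2 (0.206); neither Vnn1 nor Ehhadh had passed. With normexp, median signal, the authors' values and no filter in that order, the correlation between sexes of 0.572 became 0.675, 0.647, 0.651 and 0.46. Pemafibrate against LKO gave −0.144, −0.126, −0.13 and 0.044 in males and −0.099, −0.098, −0.101 and 0.06 in females. Pemafibrate in males against LKO in females gave −0.36, −0.365, −0.368 and −0.277, and the other pairing −0.1, −0.146, −0.146 and −0.101. The cause was not tested.

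Leaving out each mouse in turn gave 2463 to 2826 genes (pemafibrate, LWT males), 4108 to 4885 (LWT females), 0 to 1 (LKO males), 3 to 30 (LKO females), 644 to 880 (LKO against LWT males), 1239 to 1866 (females), 735 to 1047 (genotype by treatment, males), 2549 to 3095 (females), 55 to 85 (sex by treatment), 39 to 61 (sex by genotype) and 6246 to 7068 (females against males). For LKO females the count was 3, 5 and 5 without vehicle replicates 1, 2 and 4, and 18, 6, 4, 6 and 30 without pemafibrate replicates 1 to 5. For LKO males it was 1 without vehicle replicate 1 or 3.

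Replicate numbers did not pair the mice: over 161 pairs of the same number the median correlation of deviations was −0.002, the lowest −0.258, and 18 lay above 0.1. With the number as a replicate block the counts were 3149, 5080, 0, 11, 872, 1748, 972, 3107, 84, 56 and 7306, each within 1.5 times of the main count, and the female-biased list in LWT males no longer passed (adjusted p = 0.0562).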

Other observations

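The lists used here were set before; the sex comparison among LKO mice was made after the result was seen. Sex differences in the liver were found without hepatocyte PPARalpha too. Among LKO vehicle mice 3312 genes were higher and 3836 lower in females, and 4650 of these 7148 differed with the same sign in LWT mice, where independent lists would share 412.1 and 599.2. Among canonical targets whose LKO effect was lower in females, Acot3 was higher in LKO females than in LKO males (3.30, SE 0.34), while Retsat (−1.76, SE 0.16) and Acaa1b (−1.01, SE 0.17) read lower than in LKO males.

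Further gene groups separated the sexes of LWT vehicle mice. Cholesterol synthesis genes were higher in females in 14 of 24 (16 adjusted over the list alone; median 0.51, adjusted p = 2.87e-07, and adjusted p = 0.398 with an estimated correlation). Genes of xenobiotic metabolism were higher in 15 of 26 and lower in 4 (15 and 5 adjusted over the list alone; adjusted p = 3.38e-06, and adjusted p = 0.0874 with an estimated correlation). T and NK cell markers were higher in 7 of 10 and lower in 1, the same adjusted over the list alone (median 0.85, adjusted p = 0.000961, and adjusted p = 0.398 with an estimated correlation). Kupffer cell markers were higher in 4 of 15 (9 adjusted over the list alone; median 0.37, adjusted p = 0.00222, and adjusted p = 0.504 with an estimated correlation). In LWT mice on pemafibrate, genes of glucose metabolism fell in 5 of 19 in females and rose in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.0111, and adjusted p = 0.177 with an estimated correlation), and genes of the unfolded protein and integrated stress response fell in 4 of 15 in males (5 adjusted over the list alone; adjusted p = 0.0193, and adjusted p = 0.419 with an estimated correlation). In vehicle LKO males cell cycle genes shifted up with 0 of 25 past the threshold, also 0 adjusted over the list alone (median 0.30, adjusted p = 5.19e-06, and adjusted p = 0.505 with an estimated correlation).

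Of the 38 lists, 32 passed in at least 1 comparison and 12 did with an estimated correlation. With pemafibrate, 17 passed in LWT males (7 with an estimated correlation), 18 in LWT females (6), 2 in LKO males (0) and 12 in LKO females (1). For LKO against LWT, 14 passed in males (1) and 11 in females (6), and for genotype by treatment 18 (8) and 17 (6). For sex by treatment 10 passed (1), for sex by genotype 16 (5) and for females against males 12 (5). Some of these lists are not described above. The 6 that passed in none were lipoprotein metabolism, bile acid synthesis and transport, the circadian clock, and markers of neutrophils, adipose tissue and skeletal muscle.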
